A study of Drosophila melanogaster with 6 samples.

How the data were processed

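The series profiled where the chromatin proteins ROW and BEAF-32 sit on the genome of Drosophila melanogaster S2 cells, a line of embryonic origin that resembles blood cells. Chromatin from sonicated nuclei was immunoprecipitated with an antibody against either protein, the immobilised chromatin was barcoded, and the DNA was sequenced. The labels give 6 samples in 2 groups, 3 with the ROW antibody and 3 with the BEAF-32 antibody. All 6 titles start with the tag con, which does not separate the groups and was not interpreted here. Groups were taken from the sample titles, because the antibody field of the BEAF-32 samples carries a number that climbs by one from sample to sample while the titles name a single antibody.

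One peak list per antibody was deposited, and the labels of all 3 samples of an antibody name the same list. Whether reads were pooled before peak calling or peaks were combined afterwards is not given in the sources used here, nor is the control library. Bowtie2, SAMtools, MACS2 and deepTools are named, without versions or roles, in the submitters' processing notes, and the genome build dm3 is named there too. The lists have no header and follow the 10-column narrowPeak layout. Column 7 of the deposited lists was read as the ratio of signal to local background at the summit, called fold enrichment here, as MACS2 writes it. Columns 8 and 9 as deposited were read as −log10 p and −log10 q of the summit. The display score that the authors deposited in column 5 was 10 times the −log10 q without its decimals in every row, so it was not used separately. Column 10 as deposited was read as the distance of the summit from the peak start. The smallest −log10 q was 1.47 in the ROW list and 1.32 in the BEAF-32 list, that is q = 0.0342 and q = 0.0483. No interval occurred more than once within a list, so each row was one peak.

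The peak lists used here hold no value for a single sample, so no spread between replicates could be computed, and every test below measures spread over peak positions or over the peaks of a list. Peaks of one list are not independent replicates. Read depth is unknown here, because the lists hold no read counts. Fold enrichment was used only to rank or describe peaks within their own list, since the scales of different antibodies cannot be compared.

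Comparisons used the peaks on the arms 2L, 2R, 3L, 3R, 4 and X, which hold 8135 of 8788 ROW peaks and 4530 of 4781 BEAF-32 peaks. Peaks were called shared when their intervals overlapped by at least 1 bp. Chance overlap came from 100000 random circular rotations of the ROW peaks along each arm, within the stretch from the first to the last peak of either list, and the p-value is that of a one-sided permutation test. The smallest p that 100000 draws can give is 1e-05. Differences in median log2 fold enrichment and correlations were tested with two-sided permutation tests of 100000 resamples. Numbers of peaks per arm were compared with the spanned length by a chi-square test and by two-sided exact binomial tests with Benjamini-Hochberg adjustment over the 6 arms of a list. These tests, and the Fisher's exact tests below, treat peaks as placed independently. Peaks lay in dense runs, so these p-values can be too small and the intervals too narrow. Shares have 95% Wilson intervals, which cover counting error only. Coordinates are on dm3, counted from 1.

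Tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The overlap test was tested on simulated data, with the real BEAF-32 peaks and 8135 simulated ROW peaks. With 30% of the simulated peaks planted on BEAF-32 summits, it recovered 30.3%. With none planted, the observed overlap was 4.77% against 4.71% by chance. Simulated peaks that were not planted were placed uniformly along each arm, so the simulation does not test p-values for peaks in dense runs.

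The tests, the sequences used, the alternatives and the rule for the peaks named were fixed before the data were examined. Named peaks are the 10 of highest fold enrichment in each list, the 10 shared pairs with the smallest sum of ranks in both lists, and the 5 strongest peaks of each list that overlapped no peak of the other antibody and had none of its summits within 1000 bp. The alternatives were stricter definitions of overlap, a −log10 q of at least 10, the 1000 strongest peaks of each list, −log10 q in place of fold enrichment, all sequences in place of the arms, peaks of similar width, and chance overlap from uniform placement or from shifts of 5 to 50 kb. A floor of 4-fold on ROW peaks was added after seeing the data. Planned tests of start sites, of gene lists and of the CGATA motif around summits need a genome and an annotation of dm3, which were not used here. Peaks are therefore given by position and not by gene.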

Results

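ROW is a zinc-finger and AT-hook protein that belongs to a complex with the heterochromatin protein HP1c, and BEAF-32 is an insulator protein that binds boundary elements between chromatin domains. Binding of both was mapped by chromatin immunoprecipitation and sequencing in S2 cells, with 3 samples per antibody and 1 deposited peak list per antibody. The lists carry no values for single samples and no read counts, so replicate error and depth could not be taken from them, and all statistics describe peaks within these lists. As far as the series title and design state it, the question was how the binding maps of both proteins relate to each other.

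The ROW list was the longer one. It held 8788 peaks that covered 5.80 Mb, against 4781 BEAF-32 peaks that covered 2.82 Mb. Median fold enrichment over local background was 4.04 for ROW (interquartile range 2.59 to 7.87) and 7.38 for BEAF-32 (3.68 to 18.1). Peaks of at least 16-fold made up 4.76% of the ROW list and 29.4% of the BEAF-32 list. Median peak width was 571 bp for ROW and 564 bp for BEAF-32. These levels describe each list and do not rank the antibodies, because antibody and depth both enter them. On the 6 chromosome arms, to which the comparisons that follow were restricted, there were 8135 ROW peaks and 4530 BEAF-32 peaks.

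Over the full lists, most BEAF-32 sites were also ROW sites, whereas a smaller share of ROW sites were BEAF-32 sites. Of the BEAF-32 peaks on the arms, 3664 of 4530 overlapped a ROW peak, a share of 80.9% (95% interval 79.7 to 82.0). Of the ROW peaks, 3611 of 8135 overlapped a BEAF-32 peak, which is 44.4% (43.3 to 45.5). The remaining 866 BEAF-32 peaks and 4524 ROW peaks were not shared. Rotated ROW positions touched 8.41% ± 0.491 (SD over 100000 rotations) of BEAF-32 peaks, so the observed share was 9.61 times that of chance. For ROW peaks the rotated share was 4.69% ± 0.274, and the observed share was 9.46 times higher. Both shares exceeded those of all 100000 rotations in a one-sided permutation test (p = 1e-05, the smallest that this number of draws can give). Shifting the ROW peaks by only 5 to 50 kb, which keeps them near their own region, raised chance to 6.67% of ROW peaks and 11.97% of BEAF-32 peaks. No shift reached the observed shares (permutation p = 1e-05). Neither kind of chance position was limited to sequence where peaks can be called. Without a control antibody, it is not known how much of the excess comes from sites that any antibody recovers. Which share was larger depended on the length of the lists: with only ROW peaks of at least 4-fold, a floor chosen after seeing the data, 57.3% of ROW and 54.6% of BEAF-32 peaks were shared. The size of the shared set depended on the definition: with summits at most 100 bp apart it was 2106 peaks, which is 25.9% of ROW and 46.5% of BEAF-32 peaks.

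Where both proteins had a peak, their summits lay close together. Over the 3680 overlapping pairs the median distance between summits was 85 bp (interquartile range 41 to 175), and 57.2% of pairs had summits within 100 bp. Pairs that overlapped after rotation had a median distance of 313 bp, and the lowest median of 1000 rotations was 254.5 bp (one-sided permutation p = 0.000999, the smallest that 1000 rotations can give; this test was added after seeing the data). The pairs with the strongest quartile of BEAF-32 peaks had a median distance of 72 bp, and those with the weakest quartile one of 117 bp. Over all ROW peaks on the arms, the nearest BEAF-32 summit was a median of 1432 bp away. A BEAF-32 summit lay within 100 bp of 25.9% of ROW peaks, and 53.8% had none within 1000 bp. Rotated ROW positions lay a median of 13712.5 bp from a BEAF-32 summit, and none of 1000 rotations gave a median under 9420 bp. One interval rarely spanned several of the other: 69 ROW peaks covered more than 1 BEAF-32 peak and 16 BEAF-32 peaks covered more than 1 ROW peak.

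**Figure D1:**
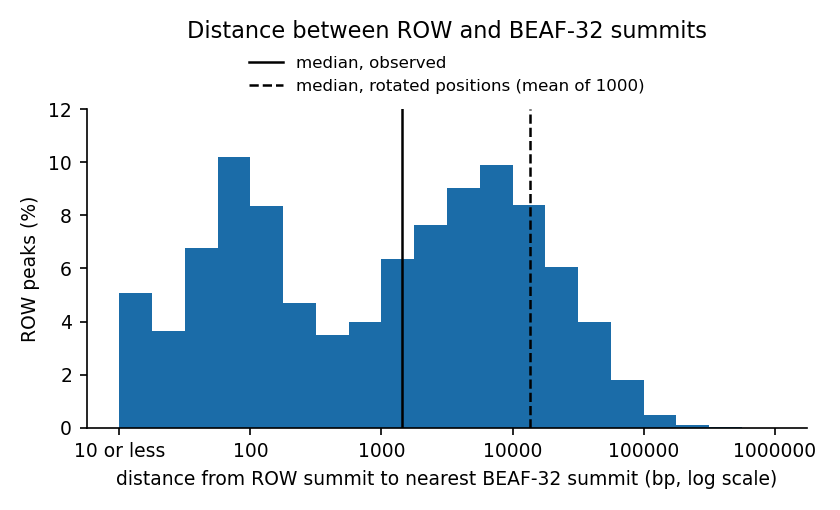
Distance from each of the 8135 ROW summits on the arms to the nearest BEAF-32 summit (x axis, bp, log scale, distances under 10 bp drawn at 10) as a percentage of ROW peaks (y axis). The solid line is the observed median of 1432 bp and the dashed line the mean median of 1000 rotations, 13712.5 bp; on this log scale the observed distances form 2 humps.

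Stronger ROW peaks were more often BEAF-32 sites. In the weakest quartile of ROW peaks (fold enrichment up to 2.68) 23.3% overlapped a BEAF-32 peak (95% interval 21.5 to 25.2). The share was 38.8% in the next quartile and 48.7% in the one after, and it reached 66.7% (64.6 to 68.7) in the strongest quartile, above 8.07-fold. Spearman's rho between ROW fold enrichment and being shared was 0.33 across peaks (permutation p = 1e-05). Shared ROW peaks had a median fold enrichment of 5.95 and unshared ones of 3.34, a log2 difference of 0.83 (permutation p = 1e-05). Shared ROW peaks were also wider, with a median of 666 bp against 495 bp. Among ROW peaks within the interquartile range of width the log2 difference was 0.53 (permutation p = 1e-05). The trend was weaker when sharing meant summits at most 100 bp apart. The shares then ran from 13.9% in the weakest to 34.3% in the strongest quartile. Spearman's rho was 0.17 and the log2 difference 0.46 (permutation p = 1e-05 for each).

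BEAF-32 peaks were shared with ROW at every strength, and stronger ones more often. The share was 72.5% (69.8 to 74.98) in the weakest quartile of BEAF-32 peaks, those up to 3.85-fold, and 89.4% (87.5 to 91.1) in the strongest, those above 18.5-fold. Spearman's rho was 0.16 across peaks (permutation p = 1e-05). Median fold enrichment was 9.14 at shared and 5.13 at unshared BEAF-32 peaks, a log2 difference of 0.83 (permutation p = 1e-05), with median widths of 594 bp and 441 bp. This difference was not seen among BEAF-32 peaks within the interquartile range of width, where the medians were 11.6 and 10.98 and the log2 difference was 0.08 (permutation p = 0.479). With summits at most 100 bp apart, the share was 32.3% in the weakest and 61.25% in the strongest quartile, and the log2 difference was 0.81. With an overlap of at least 50% of both intervals the log2 difference was 1.35 (permutation p = 1e-05 for each difference). At that overlap the median width was 610 bp at shared and 452 bp at unshared BEAF-32 peaks. Neither stricter definition was tested among peaks of like width.

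**Figure D2:**
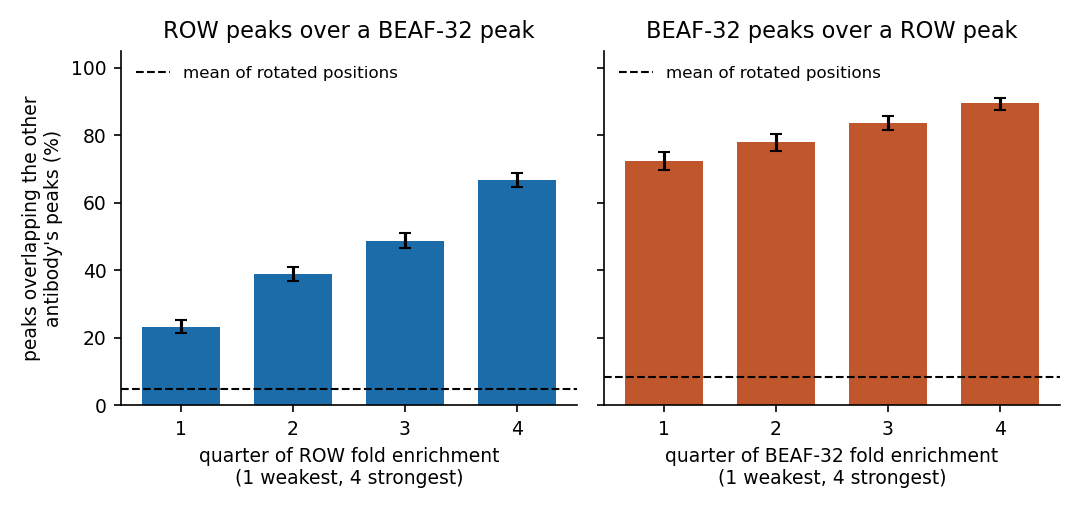
Share of peaks (y axis, percent) that overlapped a peak of the other antibody by at least 1 bp, by quartile of the peak's own fold enrichment (x axis), for ROW peaks on the left and BEAF-32 peaks on the right. Bars are shares with 95% Wilson intervals and dashed lines the mean of 100000 rotations; ROW bars rise from 23.3% to 66.7% and BEAF-32 bars from 72.5% to 89.4%.

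At shared sites the strengths of both proteins were only loosely related. Across the 3680 pairs on the arms, Spearman's rho between ROW and BEAF-32 fold enrichment was 0.15 and Pearson's r of the log2 values was 0.15 (permutation p = 1e-05 for each). Without the 2 pairs farthest from the median ROW strength, rho stayed at 0.15. The median ROW fold enrichment was 4.89 under the weakest quartile of BEAF-32 peaks and 7.11 under the strongest quartile. Pairs are not independent replicates. Restricting each list to its 1000 strongest peaks left 246 shared peaks, 24.6% of each list against 1.21% by chance (permutation p = 1e-05).

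The strongest single sites showed both shared and separate binding. The strongest ROW peak on the arms, on 2R from 2234807 to 2235605, had a fold enrichment of 29.80 and its summit fell on the same base as a BEAF-32 summit. The next ROW peaks lay on 3R from 11054963 to 11055549 (28.26-fold, 36 bp from a BEAF-32 summit) and on X from 22027276 to 22027857 (27.38-fold, 2 bp away). Of the 10 strongest ROW peaks, 9 overlapped a BEAF-32 peak, with the nearest BEAF-32 summit up to 704 bp away. The exception lay on 3R from 27413932 to 27414556, with a fold enrichment of 25.29 and the nearest BEAF-32 summit 7597 bp away. Among the 10 strongest BEAF-32 peaks 8 overlapped a ROW peak. The strongest, on X from 1235731 to 1236414, had a fold enrichment of 34.09 and a ROW summit 241 bp away. The BEAF-32 peak on 2L from 19508397 to 19509064 (33.52-fold) had a ROW summit 6 bp away. The 2 without a ROW peak were on X from 926964 to 927435 (33.74-fold, nearest ROW summit 19638 bp away) and on 2R from 16449549 to 16450157 (32.63-fold, 10177 bp away).

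Sites that ranked high in both lists at once lay on 2L, 2R, 3L and 3R. The pair with the best sum of ranks was on 3L, with ROW from 8190829 to 8191511 at 19.78-fold and BEAF-32 from 8190692 to 8191382 at 31.14-fold, and its summits were 185 bp apart. It was followed by a pair on 3R with ROW from 19783902 to 19784584 at 20.84-fold and BEAF-32 at 29.67-fold, 112 bp apart. A pair on 3L around 6481715 had the closest summits of the 10, 16 bp apart, at 22.73-fold for ROW and 28.44-fold for BEAF-32. Among peaks on their own, the 5 strongest ROW peaks lay on 3R (3 peaks), 3L and 2L. They included the ROW peak with the highest −log10 q of the list, 3914.38, on 3R from 24983233 to 24983956 (24.36-fold), where the nearest BEAF-32 summit was 4411 bp away. The other 3 strongest BEAF-32 peaks without ROW were on 3L from 15603226 to 15603798 (31.24-fold), on 2R from 19744161 to 19744784 (31.17-fold) and on 2L from 7203998 to 7204638 (30.72-fold). These single sites have no replicate check.

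Over all peaks of the lists, both proteins were denser on the small chromosome 4 and sparser on the X than the lengths of the arms predict. Among peaks of −log10 q of at least 10, only the excess of BEAF-32 on chromosome 4 held. Read depth per arm is not known, so a difference in peak calling cannot be told apart from one in binding. Chromosome 4 had 137 ROW peaks, 110.1 per Mb and 1.62 times the expected number (95% interval 1.37 to 1.92), and 76 BEAF-32 peaks, 61.1 per Mb and 1.62 times the expected number (1.28 to 2.02). Adjusted p-values of exact binomial tests were 5.763e-07 for ROW and 0.000272 for BEAF-32. The X had 1346 ROW peaks, 0.89 times the expected number (0.84 to 0.93, exact binomial adjusted p = 2.892e-06), and 776 BEAF-32 peaks, 0.92 times (0.86 to 0.98, exact binomial adjusted p = 0.0179). Arm 2R was denser in both lists, at 1.07 times for ROW and 1.14 times for BEAF-32 (exact binomial adjusted p = 0.00446 and 7.371e-05). Arm 2L had fewer BEAF-32 peaks than its length predicts, at 0.93 times (exact binomial adjusted p = 0.0288). Over all arms the distribution departed from length for ROW (chi-square 62.4, p = 3.921e-12) and for BEAF-32 (chi-square 44.7, p = 1.66e-08). These p-values and intervals treat peaks as independent although they lie in dense runs, so the p-values can be too small. With only peaks of −log10 q of at least 10, the ROW calls on 4 (1.12 times), X (0.97 times) and 2R (1.07 times) and the BEAF-32 call on X (0.96 times) did not pass, and the BEAF-32 calls on 4 (1.53 times), 2R and 2L did. The median fold enrichment of ROW peaks was 2.59 on chromosome 4 and 4.67 on the X.

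The share of BEAF-32 peaks that overlapped ROW was similar on the major autosomal arms and lower on the X. It was 82.9% on 2L, 81.4% on 2R, 82.0% on 3L and 83.4% on 3R, with 95% intervals that overlap. Chromosome 4 had 88.2% (79.0 to 93.6), and the X had 72.8% (69.6 to 75.8). The X minus all autosomes gave −9.74 percentage points (95% interval −13.2 to −6.48, two-sided Fisher's exact p = 1.461e-09), and the X also carried fewer ROW peaks per Mb. The X was set against the autosomes only after the shares per arm had been seen, and Fisher's test treats neighbouring peaks as independent. ROW peaks overlapped BEAF-32 in 42.6% of cases on 2L, 47.2% on 2R, 42.5% on 3L, 47.4% on 3R, 41.6% on 4 and 41.7% on the X. The X share was set against 44.9% on all autosomes (difference −3.25 percentage points, −6.11 to −0.342, two-sided Fisher's exact p = 0.0306). It was close to the shares on 2L, 3L and 4, so this difference does not set the X apart from every autosomal arm.

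**Figure D3:**
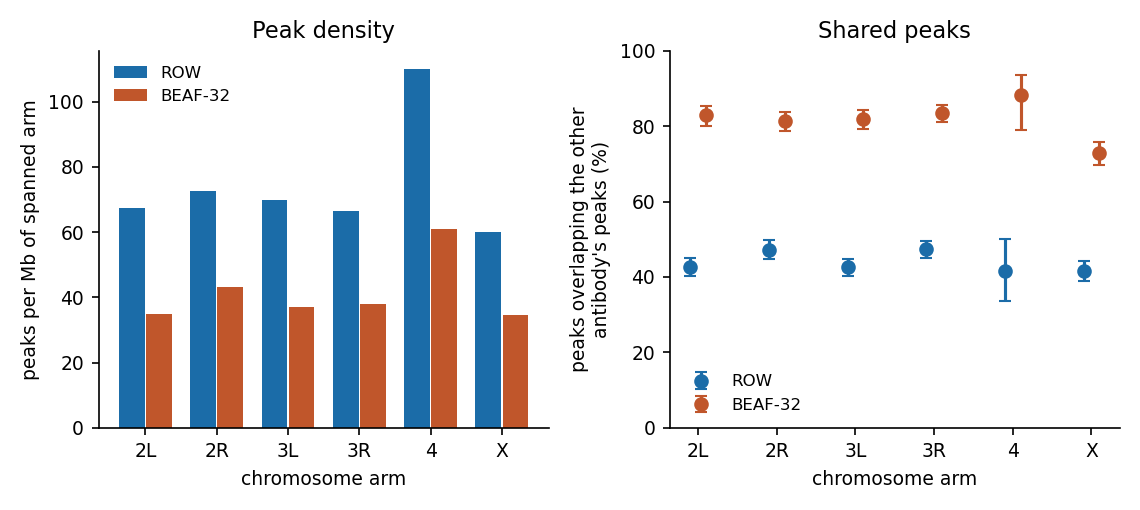
Left, peaks per Mb (y axis) on each chromosome arm (x axis), over the stretch from the first to the last peak, for ROW and BEAF-32. Right, share of each antibody's peaks that overlapped the other's (y axis, percent, with 95% Wilson intervals); the BEAF-32 share is 72.8% on the X and 81.4% or more on the other arms.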

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

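The tests in this part were chosen after the results were seen. Both lists hold peaks on sequences that the comparisons did not use: heterochromatic pieces, unplaced scaffolds and the mitochondrial sequence, with 653 ROW and 251 BEAF-32 peaks in all. Whether these peaks, those on the mitochondrial sequence included, reflect binding could not be tested, because the control library is not known. On the mitochondrial sequence there were 7 ROW and 9 BEAF-32 peaks, of which 6 and 8 overlapped, against a chance share of 71.6% and 56.7% on so short a sequence (permutation p = 0.349 and 0.015). Their median fold enrichment was 3.88 for ROW and 4.52 for BEAF-32, with maxima of 11.2 and 7.31. The medians on the arms were 4.16 and 7.88, so fold enrichment does not separate the mitochondrial ROW peaks from those on the arms. Of the 251 BEAF-32 peaks outside the arms, 90.8% overlapped a ROW peak, against 5.09% by chance (permutation p = 1e-05) and 80.9% on the arms.

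Outside the arms 35 ROW peaks reached at least 16-fold, and all 35 were on the unplaced scaffolds U and Uextra. Of these, 48.6% (17 peaks) overlapped a BEAF-32 peak, against 74.9% of the 383 ROW peaks of that strength on the arms (two-sided Fisher's exact p = 0.00229). Repeat copies that raise both antibodies alike were assumed to give a share at least as high as on the arms, but this share cannot decide against them. The 35 peaks may not be independent sites, and the lists differ in what they show on U and Uextra. There 91.8% of 134 BEAF-32 peaks overlapped ROW, against 80.9% on the arms. Of 330 ROW peaks there 36.7% overlapped BEAF-32, against 44.4% on the arms. Repeats bound by ROW alone and wrongly placed reads that differ between libraries stay open too, because the control library and the read depth are not known. No biological explanation was tested, since the design has no group that separates these sequences.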

How the results depend on the processing

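No paired analysis was possible because each antibody has 1 list for its 3 samples, and for the same reason leaving out each sample in turn was not possible. The tests of start sites, gene lists and the CGATA motif were not run. Of 70 recalculations of the 12 main results, 69 kept direction and side of the threshold. Of these, 4, with a 4-fold floor on ROW peaks, were added after the data were seen and gave shares of 57.3% for ROW and 54.6% for BEAF-32. The exception was the log2 difference in BEAF-32 fold enrichment between shared and unshared peaks, 0.0795 among peaks of middle width against 0.83 over all. The cause was not tested. The count of 69 overstates what was checked. Each share and its ratio to chance were counted as separate results with the same p-value, and a chi-square has no direction to reverse. Counting every row as a peak was included and could not differ. Ratios for single arms were not among the 70. Of their recalculations 23 stayed the same, 3 called ratios changed sign, 8 others lost their call and 2 gained one. Shares of shared peaks ranged from 24.6% to 57.3% for ROW and from 24.6% to 81.4% for BEAF-32 over the definitions of overlap and strength. The ratio to chance for ROW ranged from 6.65, with local shifts, to 33.9, with summits at most 100 bp apart; a smaller target lowers chance by construction. Counting every row as a peak changed nothing, because no interval is repeated. With expected numbers per arm taken from the other antibody instead of length, 4 log2 ratios changed sign: ROW on 2L, not called by length, became 0.097, ROW on 2R became -0.09004, BEAF-32 on 4 became -0.0055 and BEAF-32 on X became 0.05008. The ROW ratios on 2L, 2R and 3L then passed the exact binomial test (adjusted p = 0.0185, 0.0185 and 0.0251), whereas ROW on 4 and X (0.931 and 0.25) and BEAF-32 on 4, X, 2L and 2R (1, 0.434, 0.116 and 0.116) did not. This expectation asks which antibody is more frequent on an arm, and both were dense on 4 and 2R. At a −log10 q of at least 10, the calls for ROW on 4, X and 2R and for BEAF-32 on X were not kept. Read depth could not be measured from the lists, which hold no read counts, so what it limits is known only as far as the tests on the X go.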

Other observations

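In this part the tests of read depth and of ROW density over all peaks on the X were written before their results were seen, and the other tests after. For weak BEAF-32 peaks, the correlation of strengths was first to count against sites that any antibody recovers if it lay under 0.3. The value found lies under 0.3, and the limit was then lowered to 0; no value in the tables supports either limit. A first test of signal that follows ROW, in which ROW was weaker under the weakest than under the strongest quartile of BEAF-32 peaks (4.89-fold against 7.11-fold), was to count against that explanation and was replaced, because signal that follows ROW gives such a trend too. The first test of false calls, the overlap with ROW itself, was replaced because it only restated the pattern.

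Peaks of both proteins came in dense runs and left long stretches empty. The densest of 482 windows of 250 kb that held any peak was on 2L from 10250001 to 10500000, with 45 ROW and 39 BEAF-32 peaks against medians of 16 and 8 per window. In it 31 ROW and 31 BEAF-32 peaks were shared. The next, on 3L from 500001 to 750000, had 44 ROW and 28 BEAF-32 peaks, of which 21 and 22 were shared. On 2R from 19750001 to 20000000 there were 34 ROW and 32 BEAF-32 peaks, of which 29 and 30 were shared. On 3R from 5250001 to 5500000 there were 40 ROW and 26 BEAF-32 peaks, of which 23 and 23 were shared. The longest stretch on the arms with no peak of either protein was on 2L from 17501438 to 17962999, 461.6 kb. It was followed by 432.7 kb on X from 11923722 to 12356431 and 348.8 kb on 3L from 13506691 to 13855491. In all 26 such stretches reached 200 kb. These windows and stretches were picked after their values were seen.

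The weakest quartile of BEAF-32 peaks overlapped ROW in 72.5% of cases, against 7.51% for rotated positions and 23.1% in the highest of 100000 rotations. Where they overlapped, the summits lay a median of 117 bp apart, against 277 bp for pairs that overlapped after rotation and 183 bp in the lowest of 1000 rotations (one-sided permutation p = 0.000999, the smallest they can give), which argues against false calls at random places as the source of the shared weak peaks. Sites that any antibody recovers stay open: over the 827 shared pairs of this quartile Spearman's rho of both strengths was only 0.0921 (bootstrap 95% interval 0.0220 to 0.161), but without a control antibody the value that such sites would give is not known. Weak BEAF-32 signal that follows the amount of ROW stays open as well. The same rho cannot decide it, because only BEAF-32 peaks up to 3.85-fold enter it and so narrow a range can lower rho. Among ROW peaks without a stronger BEAF-32 peak, 9.67% of the weakest and 26.7% of the strongest ROW quartile had a weak one (difference 17.1 percentage points, 13.9 to 20.3), but this largely restates the rise of sharing with ROW strength.

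BEAF-32 peaks on the X overlapped ROW less often than those on the autosomes, 72.8% against 82.6%, and a different mix of strong and weak peaks does not account for it, since the share on the X standardised to the autosomal mix was 71.2% (68.0 to 74.4). Median −log10 q on the X at like fold enrichment was 0.739 to 1.07 times that on the autosomes for ROW and 0.974 to 1.37 times for BEAF-32, over classes from 2-fold to 16-fold: lower for ROW peaks above 4-fold, and higher for most BEAF-32 classes. Lower depth that hides only ROW peaks near the calling threshold is argued against as the whole cause. BEAF-32 peaks of at least 16-fold overlapped ROW peaks of at least 4-fold in 57.4% of cases on the X and 68.1% on the autosomes (difference −10.8 percentage points, −17.3 to −4.39, two-sided Fisher's exact p = 0.00101). The −log10 q of these ROW peaks on the X was never under 27.2. Lower depth that also reduces the measured fold enrichment, and so moves ROW peaks under the 4-fold cut, stays open. The test cannot decide it, because read depth and the control library are not known. Fewer ROW peaks on the X stay open. Over all ROW peaks the ratio to chance was 9.85 on the X (9.41 to 10.3) and 9.57 on the autosomes (9.43 to 9.71). A ratio on the X at least as high as on the autosomes was the prediction written beforehand for this explanation. In the test written afterwards, ROW peaks of at least 4-fold were 0.977 times as many on the X as its length predicts (0.915 to 1.04). They still overlapped fewer BEAF-32 peaks on the X (47.0% against 56.2%, difference −9.17 percentage points, −13 to −5.31). The interval of 0.915 to 1.04 still allows a small shortage. Dosage compensation, which acts on the X of these male cells, was not tested.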
